A study of Mus musculus with 24 samples.

How the data were processed

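Liver total RNA of 24 mice in 6 groups of 4 was sequenced, and 15 tables of 1 deposited workbook were used. Each table holds, for a pair of groups, the counts of 8 libraries beside DESeq2 statistics. Per the submitters' processing notes the authors counted reads per gene with HTSeq and tested them with DESeq2 on build GRCm38 (versions none given). The aligner, its settings and the annotation release are not given in the sources used here. The deposited counts are raw read counts per gene, per the file headers and their whole-number values. The deposited mean signal (baseMean) is the mean of counts divided by DESeq2 size factors, checked by recovering it from the counts. The authors' log2 fold change is the second group over the first, moderated toward 0 in the tables cut at an adjusted p and not moderated in the least filtered ones. The authors' p-values and adjusted p-values are as deposited. The vehicle and PCN table is the only one that holds nearly all genes (19650 listed, and 2154 of the genes that its statistics imply are not listed). All others hold genes selected on their own result, so their calls are the authors' own, described with the counts of the listed genes.

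Columns were assigned to groups from the table names and column order (120 per-sample columns mapped, 0 unused), and the same library gave the same counts in every table that holds it. Vehicle and pravastatin columns carry sample numbers that tie them to animals per the labels, and other columns are known by group only. Library numbers in the text are column order. Accession numbers in the identifier column were out of register with the gene symbols in 3 tables (0.01%, 0.65% and 0.19% of lines matched), so genes were joined by symbol and coordinates. Start positions in the tables count from 0 and were raised by 1. One table named for an adjusted p of 0.1 holds 1333 genes that all stand in the table for 0.05 and was not used for counts. No library was a copy of another (lowest chi-square per degree of freedom 5.72).

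Size factors of each table were recovered by least squares from baseMean and the counts (error at most 0.0288% in simulated tables). Tables were set on 1 scale through the groups they share, at 12.3 M counts per library. The shared groups' ratios varied by at most 0.286% over libraries, and the 2 routes to PXRKO atorvastatin differed by −0.216%. Levels across groups are therefore set across separately normalised tables. Folds in the text are ratios of group means on this scale.

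For PCN against vehicle, edgeR 4.0.16 was run with TMM, filterByExpr and the quasi-likelihood F test on 12938 genes, at adjusted p (Benjamini-Hochberg) of 0.05. For the other comparisons the authors' calls at that threshold are reported, and beside them edgeR on the listed genes: the recovered size factors, with the dispersion trend and quasi-likelihood prior (5.82 degrees of freedom) learned on the vehicle and PCN table, and adjustment over the number of genes that the authors' adjusted p implies. On 1047 listed genes of the vehicle and PCN libraries this fit and the full fit gave 362 and 360 genes at p under 0.001, 357 in both. The trend and prior were learned on these same libraries, so close results were built in. Use of the fit on the statin and PXRKO libraries was not checked by this. The genotype by atorvastatin interaction and the direct comparisons of compounds used the same fit on genes listed for all groups concerned. Intervals are at 95%. Other tools were R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

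The 28 fixed gene lists, cell type markers among them, were written without the data. With PCN they were tested with camera (limma) at a preset correlation of 0.01, and with an estimated correlation beside it, for lists of at least 5 measured genes. With the authors' calls they were tested by a one-sided Fisher's exact test against genes of the vehicle and PCN table at or above the lowest called baseMean, which treats genes as independent. Adjustment was over the lists of a comparison. Counts adjusted over the list alone use the p-values of the list's own members, a member that a selected table leaves out counting as not passed. Overlap of atorvastatin and PCN shares its vehicle libraries, so it was set against controls split 2 and 2 and against simulated tables with no effect.

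Genes named in the text follow a rule set in advance: Nr1i2, then genes past the threshold with a mean of at least 50 normalised counts and no overlap between groups, the 8 with the largest rise and the 8 with the largest fall, then up to 3 called members per list, with predicted gene models left out, and for tests of a difference the 8 largest. The text gives part of these, and some are not reported here. Genes outside the rule (Hspa5, Asns, Cry2, Tef, Bhlhe40, Noct, Fdps, Tm7sf2, Npas2 for pravastatin, and Insig1, Pim1 or Usp2 in tests of a difference) were chosen after their values were seen.

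The fit was tested on 3 simulated tables with the depth and dispersion of the PCN comparison and 200 changed genes each. It called 49.2% of genes changed 1.5-fold (89 of 181), 74.0% at 2-fold (162 of 219), 95.0% at 4-fold (190 of 200) and 28 of 38214 unchanged genes. Camera called the changed set and 4 of 100 null sets. Genes were simulated independently, so this does not test the preset correlation on the real lists, where the estimate reached 0.719 (Kupffer markers).

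Alternatives tried were DESeq2 in place of edgeR or the reverse, DESeq2 size factors, no filter, a mean of at least 50 normalised counts, an adjusted p of 0.1, an absolute log2 fold change of at least 1, leaving out each library, and animal-number range (limit 750) as a covariate for pravastatin. Folds of the genes given with values were also computed with each library left out, chosen after seeing the data, and are printed where they moved more than 1.5-fold. Overlaps of calls were also set against 20 simulated data sets without effects and with shared vehicle libraries, chosen after seeing the data, taking from each comparison the genes of the lowest p (edgeR), as many as the authors called, that moved the same way. Per gene, 4 libraries against 4 lie wholly apart by chance in 2.86%. Genes called on the same libraries are picked in part for such a gap, so this is not their expected rate.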

Results

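Liver RNA from 24 male mice was sequenced in 6 groups of 4 animals. Wild-type (WT) mice received vehicle (distilled water), pravastatin (10 mg/kg), atorvastatin (10 mg/kg) or pregnenolone 16α-carbonitrile (PCN, 100 mg/kg), an agonist of mouse PXR, and PXR knockout (PXRKO) mice received vehicle or atorvastatin (10 mg/kg). Dosing was oral for 4 days and ended with a 12 h fast. Per the labels each replicate is a separate animal, since every title carries its own animal number, and the WT and PXRKO animals came from separate experiments, so genotype and experiment cannot be separated here. Total RNA libraries (ribosomal RNA removed) held 11.2, 24.6, 6.64 and 17.0 M counts in listed genes for WT vehicle and 14.7, 8.75, 8.16 and 16.3 M for PCN. The other groups are listed only for selected genes, and their depth is known as a size factor (1 stands for 12.3 M counts, M for 1e6): 1.57 to 1.82 for pravastatin, 1.03 to 1.43 for WT atorvastatin, 0.771 to 1.28 for PXRKO vehicle and 0.636 to 1.13 for PXRKO atorvastatin. Levels are normalised read counts set on 1 scale across separately normalised tables, as mean ± SD with n = 4 libraries.

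Nr1i2, which encodes the targeted receptor PXR, was read in every library of the 5 groups for which it was listed. The 12 WT libraries lay between 1068 and 1665 and the 8 PXRKO libraries between 398 and 659, with means of 1255 ± 136 in WT vehicle, 1500.0 ± 118 in WT atorvastatin, 1360.1 ± 202 with PCN, 605 ± 53.0 in PXRKO vehicle and 570.1 ± 116 in PXRKO atorvastatin (SD, n = 4). Nr1i2 fell in PXRKO vehicle to 0.482 of WT vehicle, with an adjusted p of 6.4e-20 in the authors' deposited table. It was not called with PCN against vehicle (adjusted p = 0.602, edgeR). Gene-level counts can include reads from exons outside the deleted part, so they check the knockout only in part.

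**Figure D1:**
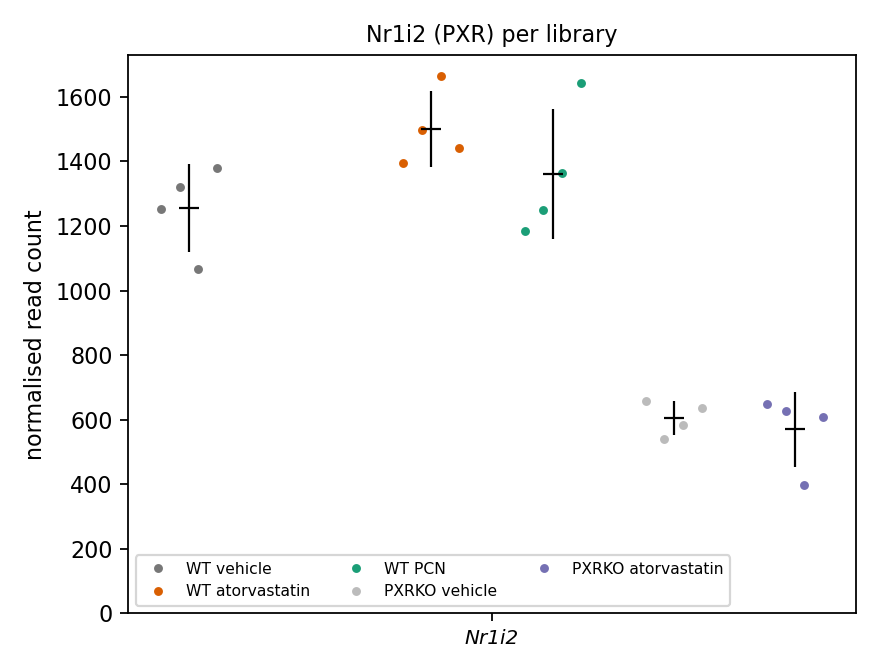
Nr1i2 per library in normalised read counts, by group; dots are libraries (4 per group) and black marks are mean ± SD. Every PXRKO library lay below every WT library, and the pravastatin group is absent because the gene was not listed for it.

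With PCN 3 PXR target genes of drug metabolism were called higher and 14 of 21 circadian clock genes were called. Cyp3a11, the main PCN-inducible drug oxidase of mouse liver, rose 2.22-fold (35842 ± 8154 to 79668 ± 25057), and the carboxylesterase Ces2a rose 2.61-fold (3112 ± 353 to 8113 ± 3285; SD, n = 4; adjusted p = 0.0135 and 0.00599, edgeR). Cyp3a44 rose from a low level (13.9 ± 4.46 to 41.7 ± 15.9, SD, n = 4), and reads can split between the closely related Cyp3a genes. Of 38 measured PXR/CAR xenobiotic targets, 3 rose, 0 fell and 35 did not pass, while 7 rose and 2 fell when adjusted over the list alone. The camera test placed this list higher (adjusted p = 0.0391, and adjusted p = 0.739 with an estimated correlation).

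Genes outside drug metabolism changed with PCN as well. Per3, a clock repressor, rose 4.07-fold (466 ± 155 to 1896 ± 481), the NAD-precursor kinase Nmrk1 rose 3.38-fold (277 ± 22.6 to 938 ± 138), and the glucocorticoid-induced Tsc22d3 fell 3.20-fold (2489 ± 388 to 777 ± 68.1; SD, n = 4). Adjusted p (edgeR) was 0.00128, 3.1e-05 and 3.1e-05. Wee1 and Usp2, both with clock-driven transcription, and the growth regulator Myc rose as well (4.50-fold, 3.27-fold and 5.16-fold; adjusted p = 0.00508 to 0.0127, edgeR). Of 21 clock genes 10 rose, 4 fell and 7 did not pass (14 and 6 adjusted over the list alone), Arntl falling 3.70-fold (136 ± 50.8 to 36.8 ± 13.1, SD, n = 4) and Npas2 falling from a low level (19.7 ± 3.83 to 1.99 ± 2.09, a fold of 9.88 that became 19.5 without PCN library 1). Camera gave adjusted p = 0.00669 for the clock list, and adjusted p = 0.517 with an estimated correlation.

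Igfbp1, an insulin-repressed secreted protein, fell 3.31-fold with PCN (563 ± 253 to 169.8 ± 50.6), the fasting hormone gene Fgf21 fell 3.13-fold (98.1 ± 27.8 to 31.3 ± 11.8), and Angptl4, an inhibitor of lipoprotein lipase, fell 1.93-fold (2899 ± 162 to 1504 ± 77.5; SD, n = 4; adjusted p = 9.8e-05 to 0.011, edgeR). The lipid droplet coat gene Plin2 fell 1.76-fold (9289 ± 918 to 5274 ± 1068, SD, n = 4). Of 32 fatty acid oxidation and ketogenesis genes 5 fell, 0 rose and 27 did not pass (7 fell and 2 rose adjusted over the list alone), and camera gave adjusted p = 0.00669 (adjusted p = 0.739 with an estimated correlation). Of 20 lipid uptake and droplet genes 3 fell and 1 rose, and of 24 fatty acid and triglyceride synthesis genes 2 rose, the lipogenic regulator Srebf1 among them (1.89-fold), and 1 fell, the elongase Elovl3 (3.00-fold). Camera called neither of these lists (adjusted p = 0.218 and 0.106). Sterol genes rose in 2 of 29, Aacs (3.20-fold) and Stard4 (1.45-fold), with no call for the list (camera, adjusted p = 0.106).

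Some stress-response genes fell with PCN. Herpud1, which serves degradation of misfolded proteins, fell 1.84-fold (9861 ± 1037 to 5345 ± 284), Atf5 fell 1.71-fold and the chaperone gene Hspa1b fell 5.44-fold (295 ± 239.8 to 54.2 ± 16.5; SD, n = 4; adjusted p = 7.2e-04 to 0.0188, edgeR). Without vehicle library 3 the fold of Hspa1b was 3.25. Of 27 unfolded protein and integrated stress response genes 4 fell, 0 rose and 23 did not pass (13 fell and 1 rose adjusted over the list alone). Among the 29 listed members vehicle library 3 was the highest vehicle library in 20, and the median PCN fold was 0.740 with it and 0.825 without it. Camera gave adjusted p = 1.6e-06 for this list (adjusted p = 0.517 with an estimated correlation) and 0.0132 for heat shock, where 3 of 12 fell (adjusted p = 0.739 with an estimated correlation). Mitochondrially encoded genes moved higher as a list with 0 of 12 past the threshold in edgeR (3 adjusted over the list alone, adjusted p = 0.000693, camera, and adjusted p = 0.517 with an estimated correlation). Kupffer cell markers moved lower in the same samples, with a median log2 change of −0.44 and 0 of 16 past the threshold in edgeR (0 adjusted over the list alone, adjusted p = 0.00669, camera, and adjusted p = 0.739 with an estimated correlation). In bile acid handling Nr0b2, the repressor SHP, fell 2.72-fold (533 ± 52.9 to 196 ± 28.6, SD, n = 4), with 3 of 21 genes lower and 1 higher.

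In all, edgeR called 459 of 12938 genes with PCN, 247 higher and 212 lower. Of them 444 had no overlap between the 4 PCN and 4 vehicle libraries (2.86% by chance in genes not selected on calls). The authors' deposited table called 773 genes, 411 higher and 362 lower, and 454 genes were called in both. Leaving out 1 library at a time moved the edgeR count between 223 and 480. The PCN dose was 10 times the statin dose by weight.

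Atorvastatin in WT mice raised nearly the whole sterol synthesis program. Idi1, an isomerase of the mevalonate pathway, rose 3.55-fold (261 ± 16.1 to 927 ± 263), the squalene epoxidase gene Sqle rose 3.68-fold (360.1 ± 45.8 to 1325 ± 490.5) and Nsdhl, a demethylation enzyme of sterol synthesis, rose 2.95-fold (346 ± 70.5 to 1019 ± 193; SD, n = 4). Their adjusted p in the authors' deposited table was 7.7e-21 to 6.4e-15. Of 30 measured sterol genes 27 rose, 0 fell and 3 did not pass (27 adjusted over the list alone; Fisher's exact test, adjusted p = 1.1e-28), and in all 27 every atorvastatin library lay above every vehicle library. Insig2, which retains the sterol sensor in the endoplasmic reticulum, fell 3.06-fold (4368 ± 1200.0 to 1427 ± 255, SD, n = 4).

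Lipogenic and fatty acid genes moved in opposite directions. Srebf1 rose 2.40-fold (1219 ± 187 to 2923 ± 291) and the fatty acid synthase gene Fasn rose 2.31-fold (4270.1 ± 1186 to 9850.4 ± 2940.0), while the peroxisomal oxidation gene Ehhadh fell 2.83-fold (10021 ± 2726 to 3538 ± 468) and Plin2 fell 1.76-fold (9289 ± 925 to 5275 ± 1019.5; SD, n = 4). The authors' deposited table gave adjusted p of 1.1e-22 to 0.00124 for these 4 genes. Of 24 fatty acid and triglyceride synthesis genes 10 rose and 3 fell (11 and 3 adjusted over the list alone; Fisher's exact test for the rise, adjusted p = 5.9e-06), Elovl3 falling 4.12-fold. Of 32 oxidation and ketogenesis genes 12 fell and 3 rose (14 and 3 adjusted over the list alone; adjusted p = 2.1e-07). Of 20 lipid uptake and droplet genes 4 fell and 2 rose, with no call for the list (adjusted p = 0.083).

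PXR/CAR targets, clock genes and acute phase genes rose with atorvastatin too. The efflux pump gene Abcb1a rose 2.33-fold (34.8 ± 7.29 to 80.9 ± 12.9) and Cyp2a5 rose 2.29-fold (5129 ± 2396 to 11735 ± 1462; SD, n = 4), and 10 of 39 PXR/CAR targets rose against 2 that fell (11 and 2 adjusted over the list alone; Fisher's exact test, adjusted p = 0.000616). Per3 rose 4.23-fold (466 ± 156 to 1971 ± 209, SD, n = 4) and Per2 rose 2.44-fold, and 12 of 20 clock genes rose and 1 fell (13 and 3 adjusted over the list alone; adjusted p = 2.9e-09). The acute phase gene Saa1 rose 7.68-fold (226 ± 76.8 to 1738 ± 282) and Saa2 7.00-fold (61.2 ± 21.5 to 428 ± 99.9; SD, n = 4), a pair of near-identical genes between which reads can split, and 7 of 28 acute phase genes rose and 1 fell (12 and 2 adjusted over the list alone; adjusted p = 0.00673). Adjusted p for these 6 single genes in the authors' deposited table was 6.0e-38 to 0.0108.

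Stress-response and male-biased genes fell with atorvastatin. Atf5 fell 1.89-fold (6647 ± 1039 to 3513 ± 234), and the endoplasmic reticulum factors Manf and Sdf2l1 fell 1.71-fold and 2.36-fold (771 ± 151 to 451 ± 99.4 and 159 ± 57.4 to 67.5 ± 15.4; SD, n = 4). Of 27 unfolded protein and stress response genes 9 fell and 0 rose (13 and 0 adjusted over the list alone; Fisher's exact test, adjusted p = 1.8e-05). Vehicle library 3 was the highest vehicle library in 13 of the 15 members with values here, and their median fold was 0.714 with it and 0.768 without it. The major urinary protein gene Mup1 fell 2.87-fold (1164 ± 318 to 405 ± 138, SD, n = 4), a member of a multigene family whose reads can be shared, and 11 of 33 male-biased genes fell and 0 rose (13 and 0 adjusted over the list alone; adjusted p = 1.9e-06). Female-biased genes rose in 5 of 21 and fell in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0356). Among cell markers no list was called, stellate cell markers rising in 3 of 15 with 1 lower and Kupffer markers falling in 1 of 16 (4 adjusted over the list alone). The authors' deposited table called 1333 genes, 762 higher and 571 lower. In 1116 of these the 4 atorvastatin libraries had no overlap with the 4 vehicle libraries (2.86% by chance in genes not selected on calls). On the listed genes edgeR called 792 (458 to 658 with 1 library left out).

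Atorvastatin and PCN moved many of the same genes, with sterol genes as the main exception. Of the genes that the authors' deposited table called with each compound, 496 were shared, 270 higher and 226 lower with both and 0 in opposite directions, where independent lists would share 74.1. In simulated data without effects, shared vehicle libraries alone gave 209 to 258 for as many genes of the lowest p. Over 1318 genes called with atorvastatin, log2 ratios of the compounds gave a Spearman correlation of 0.915. It was 0.862 when each compound was set against a different 2 of the 4 vehicle libraries. Shared controls alone gave 0.471 in simulated data. The genes were picked on calls against all 4 vehicle libraries, which can raise both observed values. The gap to 0.471 is therefore not a measure of a common effect alone. Per3 stood at 1971 ± 209 with atorvastatin and 1896 ± 481 with PCN, and Usp2 at 1440.1 ± 224 and 1259 ± 177 (SD, n = 4). In the direct edgeR test Per3 did not differ, with a log2 difference of 0.06 (95% interval −0.38 to 0.49, adjusted p = 0.904), nor did Usp2, 0.19 (95% interval −0.38 to 0.77, adjusted p = 0.737). All 12 clock genes called with both compounds moved in the same direction.

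Sterol genes were higher with atorvastatin than with PCN. In this direct edgeR test Nsdhl differed by a log2 value of 1.64 (95% interval 1.22 to 2.06, adjusted p = 7.0e-04), Cyp51, the lanosterol demethylase gene, by 1.46 (95% interval 1.10 to 1.83, adjusted p = 7.0e-04) and Saa1 by 2.24 (95% interval 1.26 to 3.22, adjusted p = 0.0198), whereas the PXR target Ces2a was lower with atorvastatin, at −1.25 (95% interval −1.67 to −0.82, adjusted p = 0.00434). Of 28 sterol genes tested 22 were higher with atorvastatin and 0 lower (26 and 0 adjusted over the list alone), and of 19 male-biased genes 5 were lower and 0 higher (11 and 0 adjusted over the list alone). Acute phase genes were higher in 2 of 19 and lower in 0 (6 and 0 adjusted over the list alone). Among 19 clock genes 0 differed in edgeR, also 0 adjusted over the list alone. The test covered the 2328 genes listed for all 3 WT groups, a set selected on calls, of which 68 differed, 50 higher and 18 lower with atorvastatin (96 by DESeq2). With 1 library left out the count was 25 to 89, with 25 without PCN library 2 and 29 without atorvastatin library 3. The doses differed, 10 mg/kg of atorvastatin against 100 mg/kg of PCN.

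**Figure D2:**
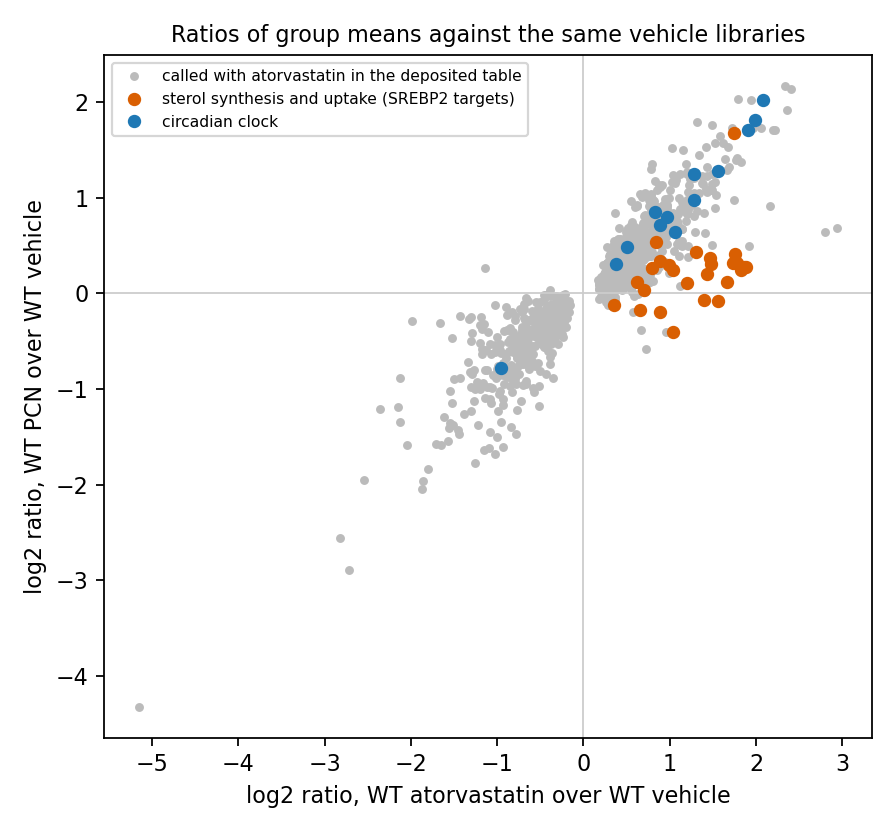
Log2 ratio of group means against the same 4 WT vehicle libraries for atorvastatin (horizontal) and PCN (vertical); each point is 1 of 1317 named genes called with atorvastatin in the authors' deposited table. Clock genes lie along the diagonal and most sterol genes lie to the right near a PCN ratio of 0.

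Few genes were called with pravastatin at the matched statin dose. Hes1, a transcriptional repressor, rose 2.31-fold (81.2 ± 25.8 to 188 ± 35.8), the kinase gene Nuak2 rose 1.77-fold (149 ± 19.6 to 264 ± 9.09) and the cytokine-signalling inhibitor gene Socs3 rose 2.04-fold (81.8 ± 13.8 to 167 ± 53.4), while the GTPase gene Arl4d fell 2.44-fold (292 ± 51.2 to 120.0 ± 26.0) and the fasting-induced Depp1 fell 1.86-fold (1072 ± 97.4 to 575 ± 155; SD, n = 4). The authors' deposited table gave adjusted p of 1.7e-09 to 0.0146 for them. It called 28 genes, 13 higher and 15 lower, of which 23 were called in the same direction with atorvastatin and 18 with PCN. In simulated data without effects, shared vehicle libraries alone gave 12 to 19 and 10 to 18 for as many genes of the lowest p. In 24 of the 28 the 4 pravastatin libraries had no overlap with the 4 vehicle libraries (2.86% by chance in genes not selected on calls). On the listed genes edgeR called 2, Nuak2 and Arl4d, with 717 at an unadjusted p under 0.05. It called 0 with the animal-number range as a covariate, and 0 to 2 with 1 library left out, 2 only without pravastatin library 3.

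No fixed list was called with pravastatin, and 0 of 28 sterol genes passed in the authors' deposited table (3 higher adjusted over the list alone). Kupffer cell markers passed in 0 of 13, with 8 lower adjusted over the list alone. Clock genes were not called, and 8 of 20 were in the least filtered pravastatin table. Of the 12 clock genes called with atorvastatin and with PCN, 5 (Per2, Per3, Cry2, Tef and Usp2) were among those 8, and in all 5 the pravastatin mean lay between vehicle and atorvastatin. The pravastatin and vehicle animals fall in lower and higher ranges of animal number with 2 animals of each group in each. Per3 stood 1.83-fold above vehicle over all animals, 2.72-fold in the lower range and 1.10-fold in the higher. Within the ranges the folds were 1.53 and 1.16 for Per2, 2.21 and 1.59 for Usp2, 1.52 and 1.06 for Cry2, and 1.49 and 1.09 for Tef, against 1.36, 1.96, 1.28 and 1.29 over all animals. In these 5 of the 8 genes both lower-numbered pravastatin animals lay farther from vehicle than both higher-numbered ones, which did not hold for Npas2, Bhlhe40 and Noct. Over all 926 listed genes the ranges parted the pravastatin libraries in 36.4% and the vehicle libraries in 32.2% (33.3% by chance).

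The statins, at the same dose, differed in sterol and clock genes. In a direct edgeR test Idi1 was higher with atorvastatin by a log2 value of 1.51 (95% interval 1.18 to 1.84, adjusted p = 3.7e-05), Sqle by 1.46 (95% interval 1.01 to 1.91, adjusted p = 3.8e-04) and Per3 by 1.20 (95% interval 0.67 to 1.74, adjusted p = 0.00389), and Insig2 differed by −1.26 (95% interval −1.62 to −0.90, adjusted p = 2.0e-04). All 4 sterol genes tested were higher with atorvastatin (4 adjusted over the list alone), and of 7 clock genes 4 were higher and 1 lower. No difference was found in edgeR for Pim1, 0.02 (95% interval −0.32 to 0.35, adjusted p = 0.954), or Socs3, −0.12 (95% interval −0.71 to 0.48, adjusted p = 0.796). Nuak2 did not pass in edgeR, at 0.35 (95% interval 0.05 to 0.64, adjusted p = 0.11), though its interval excludes 0. Of the 425 genes listed for both statins, a set selected on calls, 68 differed, 44 higher and 24 lower with atorvastatin (71 by DESeq2). The lower count moved most: without atorvastatin library 1 there were 41 higher and 13 lower. Without pravastatin library 3 or 4 there were 35 and 15, and TMM on the shared genes gave 40 and 32.

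Between the vehicle groups, genes were called higher and lower in PXRKO livers. Slco1a4, an organic anion transporter gene and PXR target, fell 9.27-fold (1449 ± 1104 to 156 ± 17.8) and the nuclear receptor gene Nr1i3 (CAR) fell 1.78-fold (7130.4 ± 771 to 3998 ± 568), whereas Ces2a rose 1.76-fold (3112 ± 354 to 5463 ± 388), Cyp2c55 rose 4.74-fold (30.1 ± 11.9 to 143 ± 58.6) and Cidec, a lipid droplet fusion gene, rose 3.81-fold (75.7 ± 27.7 to 288 ± 86.2; SD, n = 4). Their adjusted p in the authors' deposited table was 2.2e-13 to 1.4e-05, and reads can split among Cyp2c genes. Without WT vehicle library 4 the fold of Slco1a4 was 5.82. Of 39 PXR/CAR targets 5 rose and 2 fell (5 and 2 adjusted over the list alone; Fisher's exact test for the rise, adjusted p = 0.0019). Of 20 lipid uptake and droplet genes 4 rose, among them the apolipoprotein gene Apoa4 (3.44-fold), and 1 fell (5 and 2 adjusted over the list alone; adjusted p = 0.0019). The protease inhibitor gene Serpinb1c rose from near the floor (4.86 ± 4.78 to 103 ± 31.2, a fold of 21.3 that became 41.4 without WT vehicle library 4), the basement membrane gene Lamb3 2.57-fold (190.2 ± 20.0 to 489 ± 45.7) and the growth-factor binding gene Igfbp2 2.58-fold (4013 ± 753 to 10349 ± 2783; SD, n = 4).

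Several marker lists moved beside these genes. Pericentral hepatocyte markers fell in 5 of 23 and rose in 0 (6 and 0 adjusted over the list alone; Fisher's exact test, adjusted p = 7.5e-05), Nr1i3 among them, while the periportal list rose in 1 and fell in 1 of 21. Endothelial markers rose in 3 of 17 (5 adjusted over the list alone; adjusted p = 0.0117), with the VEGF receptor gene Kdr rising 1.30-fold (798 ± 20.0 to 1037 ± 26.0, SD, n = 4), and adipose tissue markers rose in 2 of 6, Cidec one of them, and fell in 1 (2 and 1 adjusted over the list alone; adjusted p = 0.0168, and adjusted p = 0.227 at a mean of at least 50). Male-biased genes rose in 3 of 33 (5 adjusted over the list alone; adjusted p = 0.0484, and adjusted p = 0.0725 at a mean of at least 50), Mup17 rising 2.24-fold. Sterol genes fell in 2 of 29, Insig1 (1.30-fold) among them, and clock genes rose in 1 of 21. The authors' deposited table called 307 genes, 173 higher and 134 lower in PXRKO. Of them 263 had no overlap between groups (2.86% by chance in genes not selected on calls). On the listed genes edgeR called 105, with 146 when PXRKO vehicle library 1 was left out and 38 to 68 without any other library. Pairs with PXRKO vehicle library 1 had a chi-square per degree of freedom of 39.8 to 110 in these genes. The other PXRKO vehicle pairs had 32.7 to 56.4. The experiment also differed between the vehicle groups, per the labels.

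Few genes were called with atorvastatin in PXRKO mice. A low count does not show a small effect. PXRKO atorvastatin libraries were shallower than WT ones (size factors 0.636 to 1.13 against 1.03 to 1.43). Depth alone is a weak reason, as PCN libraries at 0.659 to 1.33 gave 773 calls in the authors' deposited table. The same PXRKO atorvastatin libraries gave 1374 calls against WT atorvastatin. In the listed genes, pairs of PXRKO vehicle libraries differed by a chi-square per degree of freedom of 31.7 to 157 (8.27 to 34.2 for PXRKO atorvastatin). The chaperone gene Calr fell 1.34-fold (7109.6 ± 543 to 5320.0 ± 424), the disulfide isomerase gene Pdia6 fell 1.36-fold (1762 ± 154 to 1298 ± 114) and Gpx1, a glutathione peroxidase gene, fell 1.30-fold (8564 ± 389.7 to 6599 ± 472), while the glycolytic Aldoc rose 1.74-fold (69.0 ± 13.5 to 120.3 ± 15.6) and Ido2, of tryptophan breakdown, rose 1.26-fold (712 ± 33.2 to 895 ± 39.4; SD, n = 4). The authors' deposited table called 12 genes, 5 higher and 7 lower, with adjusted p of 0.00684 to 0.0499 for these 5. On the listed genes edgeR called 0, with 537 at an unadjusted p under 0.05. In 11 of the 12 the groups had no overlap (2.86% by chance in genes not selected on calls).

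Stress-response genes were the only list called in PXRKO mice, with 2 of 26 lower (12 lower and 1 higher adjusted over the list alone; Fisher's exact test, adjusted p = 0.00319). PXRKO vehicle library 4 was the highest PXRKO vehicle library in 10 of the 13 members with values here, and their median fold was 0.736 with it and 0.769 without it. Hspa5, the main chaperone of the endoplasmic reticulum, stood at 9619 ± 1702 in PXRKO vehicle and 7251 ± 1019 in PXRKO atorvastatin, and Manf at 821 ± 183 and 522 ± 102 (SD, n = 4), without a call for either gene. Of 12 such genes lower in the least filtered PXRKO table, 8 had also been called lower in WT mice with atorvastatin. Acute phase genes passed in 0 of 27 (11 lower adjusted over the list alone). Sterol genes passed in 0 of 28, also 0 adjusted over the list alone, and only Fdps and Tm7sf2 were in the least filtered PXRKO table, where the authors' deposited table gave them log2 changes of 1.18 and 0.40 with adjusted p of 0.67 and 0.54.

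The difference between genotypes in the atorvastatin effect was tested directly. Insig1, a sterol-regulated brake on sterol synthesis, stood at 2386 ± 147 and 4881 ± 1341 in WT vehicle and atorvastatin and at 1832 ± 294 and 2009 ± 538 in PXRKO (SD, n = 4). The log2 response in PXRKO minus that in WT (edgeR) was −0.90 (95% interval −1.45 to −0.35, adjusted p = 0.0309) for Insig1 and −3.66 (95% interval −5.15 to −2.18, adjusted p = 0.00378) for the acute phase gene Orm2. Tm7sf2, a sterol reductase gene, did not pass in edgeR, at −0.39 (95% interval −0.75 to −0.03, adjusted p = 0.159). Its interval excludes 0, and it passed when adjusted over the list alone. For Fdps, of the mevalonate pathway, no difference was found in edgeR, −0.52 (95% interval −1.91 to 0.87, adjusted p = 0.756). The response in PXRKO was more negative in 3 of 5 sterol genes tested (4 adjusted over the list alone), in 4 of 8 acute phase genes (5 adjusted over the list alone) and in 0 of 11 stress-response genes in edgeR (0 adjusted over the list alone). All 11 acute phase genes listed for both PXRKO groups had a lower mean with atorvastatin (median fold 0.781), while the WT median was 1.38 over 19 listed genes. These medians cover different selected genes. Over WT vehicle the median fold was 1.27 for PXRKO vehicle (12 listed genes) and 0.910 for PXRKO atorvastatin (19 listed genes). Tested were the 357 genes listed for all 4 groups, a set selected on calls, and 41 differed (81 at an unadjusted p under 0.05, and 44 by DESeq2). Of the 41, the response in PXRKO was more positive in 16 and more negative in 25. Without WT atorvastatin library 3 these counts were 15 and 15, and with TMM on the shared genes 21 and 24.

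**Figure D3:**
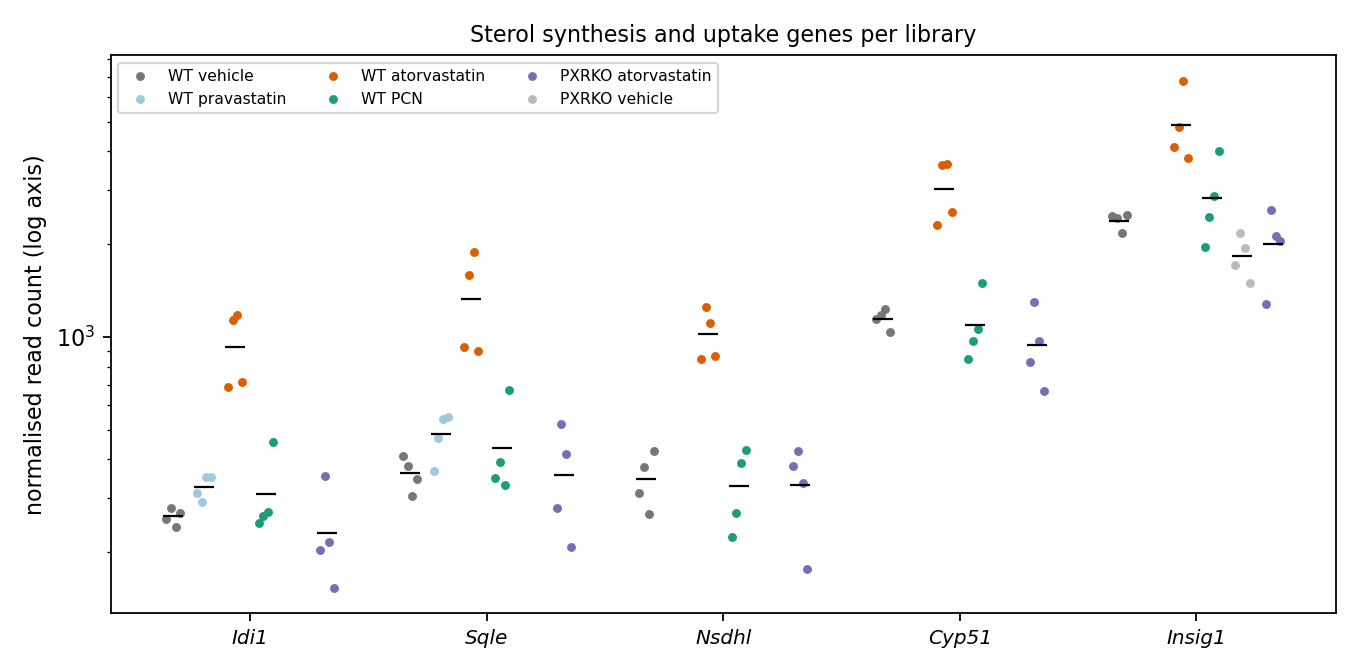
Sterol synthesis and uptake genes per library, in normalised read counts on a log axis, by group; dots are libraries and black marks are group means. The WT atorvastatin mean stands above those of the other groups, and a group is absent where the gene was not listed for it.

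Under atorvastatin PXRKO and WT livers differed in sterol, acute phase and fatty acid genes. Idi1 was 4.00-fold lower in PXRKO (927 ± 263 to 232 ± 86.4), Cyp51 3.20-fold lower (3024 ± 697 to 944 ± 271) and Saa1 7.24-fold lower (1738 ± 282 to 240.2 ± 124), whereas Ehhadh was 3.80-fold higher (3538 ± 466 to 13456 ± 4234) and Atf5 2.34-fold higher (3513 ± 232 to 8225 ± 1349.5; SD, n = 4). Adjusted p in the authors' deposited table was 1.0e-22 to 1.4e-10 for these genes. Sterol genes were lower in 28 of 30 (Fisher's exact test, adjusted p = 5.5e-32), acute phase genes in 14 of 29 (1.3e-09), female-biased genes in 12 of 23 with 2 higher (6.0e-09) and fatty acid synthesis genes in 9 of 24 with 2 higher (1.7e-05), the counts adjusted over the list alone being 28, 14, 12 and 9. Oxidation and ketogenesis genes were higher in 11 of 33 with 2 lower (adjusted p = 4.4e-06, Fisher's exact test) and male-biased genes in 10 of 33 (2.2e-05), with 11 and 10 adjusted over the list alone. Only called genes are listed for this comparison. Counts over the list alone, here and for the lists below, thus cannot exceed the calls and add no evidence.

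Clock genes were lower in 10 of 21 and higher in 4 (10 and 4 adjusted over the list alone; Fisher's exact test, adjusted p = 3.9e-07). Per2 was 3.22-fold lower (1159 ± 114 to 359.5 ± 118) and Usp2 4.46-fold lower (1440.2 ± 224 to 323 ± 149; SD, n = 4). Of the 12 clock genes called with atorvastatin and PCN in WT mice, 9 were called here against the direction of the drugs, and 0 were called between the vehicle groups in the authors' deposited table. Bile acid genes were lower in 7 of 22 and higher in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.000625), the uptake transporter gene Slc10a2 by 2.95-fold. PXR/CAR targets were lower in 8 of 40 and higher in 6 (8 and 6 adjusted over the list alone; adjusted p = 0.00497), Abcb1a by 2.92-fold. Pericentral markers were lower in 6 of 23 and higher in 3 (6 and 3 adjusted over the list alone; adjusted p = 0.00497). The authors' deposited table called 1374 genes, 625 higher and 749 lower in PXRKO. Of them 1175 had no overlap between groups (2.86% by chance in genes not selected on calls). On the listed genes edgeR called 951 (585 to 864 with 1 library left out).

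**Figure D4:**
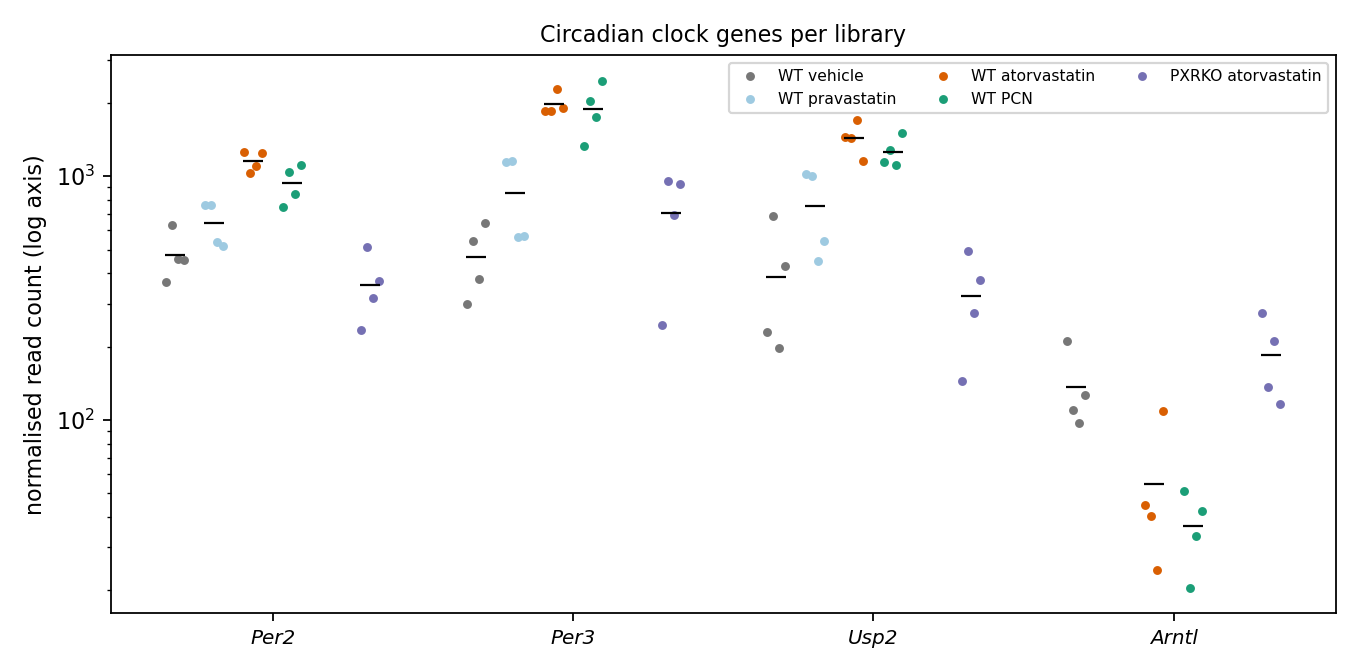
Clock genes per library, in normalised read counts on a log axis, by group; dots are libraries and black marks are group means. In Per2, Per3 and Usp2 the WT atorvastatin and PCN libraries lie above WT vehicle and PXRKO atorvastatin, while for Arntl, not called with atorvastatin against vehicle, those 2 WT groups overlap, and a group is absent where the gene was not listed for it.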

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

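The tests of explanations in this part, counts over other splits of the libraries included, were written only after the results were seen, while the interaction test was set before the data were examined.

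Among 180 groups of 4 libraries behind the genes given with values, 19 held 1 library far from the other 3 by Dixon's test at 95%, where chance gives about 1 in 20 (9.00 groups). In the WT vehicle group the highest library stood at 11561 for Hspa5 (library 3, the others 7809 to 8246), 994 for Manf (library 3, the others 684 to 721), 941 for Igfbp1 (library 4, the others 417 to 468), 650.0 for Hspa1b (library 3, the others 124 to 204), 47.8 for Cyp2c55 (library 4, the others 22.1 to 25.2), 12.0 for Serpinb1c (library 4, the others 1.84 to 3.47) and 828 for Kdr (library 1, the others 787 to 789.9). In the PCN group the highest library stood at 6867 for Plin2 (library 3, the others 4653 to 4904). In the WT atorvastatin group the highest library stood at 2282 for Per3 (library 3, the others 1848 to 1903), 611 for Mup1 (library 2, the others 315 to 355) and 667 for Gas6 (library 4, the others 404 to 433). In the WT atorvastatin group the lowest library stood at 5457 for Fasn (library 4, the others 11069.6 to 11667). In the PXRKO atorvastatin group the highest library stood at 8769 for Hspa5 (library 4, the others 6576 to 6842), 674 for Manf (library 4, the others 453 to 484), 19719.8 for Ehhadh (library 4, the others 10766 to 12032) and 382 for Gas6 (library 4, the others 299 to 311). In the PXRKO atorvastatin group the lowest library stood at 398 for Nr1i2 (library 3, the others 608 to 648). In the PXRKO vehicle group the highest library stood at 229 for Cyp2c55 (library 1, the others 105 to 125). In the PXRKO vehicle group the lowest library stood at 421 for Lamb3 (library 1, the others 506 to 520.0). No explanation was tested for these.

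Between the genotypes 7 genes given in the text were marked because their atorvastatin response differed in the interaction test (log2 response in PXRKO minus WT, edgeR): Tspan4 −1.32 (95% interval −1.69 to −0.95, adjusted p = 2.4e-04), Orm2 −3.66 (95% interval −5.15 to −2.18, adjusted p = 0.00378), Tnxb −1.37 (95% interval −1.96 to −0.78, adjusted p = 0.00583), Slc25a25 −1.26 (95% interval −1.83 to −0.69, adjusted p = 0.00767), Gas6 −1.16 (95% interval −1.73 to −0.59, adjusted p = 0.00969), Itih4 −1.37 (95% interval −2.04 to −0.69, adjusted p = 0.00969) and Insig1 −0.90 (95% interval −1.45 to −0.35, adjusted p = 0.0309). Over 100 drawn splits of the 16 libraries, 3, the real one included, gave at least the real 41 genes, with 79 as the highest other. The splits with 79, 61 and 40 genes kept the WT libraries as they are and mixed the PXRKO ones. Since the 357 genes were selected on calls, chance cannot be excluded from these splits.

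Clock genes shifted alike with atorvastatin and PCN against the same WT vehicle libraries, 12 of 12 in the same direction. If the WT vehicle libraries alone stood apart from every other group, PXRKO atorvastatin should resemble WT atorvastatin. Of the 12 genes 9 differed between them against the direction of the drugs. The PXRKO animals came from a separate experiment, which may differ in clock genes by itself, so this cannot decide the question. A time of dissection following the order of animal numbers may contribute, since numbers rise from vehicle to pravastatin, atorvastatin and PCN within each range and in 5 of 8 clock genes listed for pravastatin (not in Npas2, Bhlhe40 and Noct) both lower-numbered pravastatin animals lay farther from vehicle than the other 2. The order would place PCN farther from vehicle than atorvastatin, which held for only 1 of the 12 genes, though 0 of 19 clock genes differed between the compounds in the direct test. The 8 genes were selected on the pravastatin result and the labels give no times, so neither this nor a response of the clock to the compounds is excluded.

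Sterol genes rose with atorvastatin in WT mice and 0 passed in PXRKO mice. In 27 of 27 called genes every atorvastatin library lay above every vehicle library, so no single WT library alone carried the rise in them. Calls made on the same libraries favour such gaps, which 1116 of all 1333 atorvastatin calls had. The 27 of 27 therefore adds little to the calls themselves. As for a rise of the same size in PXRKO mice that the test missed, 3 of 5 genes had a smaller response in the interaction test. A larger response was found in 0. These 5 were selected on calls from the same libraries, and the other genes have no PXRKO vehicle values, so this is not settled. Over all 29 listed, PXRKO atorvastatin had a median fold of 0.954 over WT vehicle (0.538 to 1.38), against 2.30 for WT atorvastatin. A smaller rise in PXRKO mice is not excluded, since all 5 had a PXRKO atorvastatin mean above PXRKO vehicle (median fold 1.32, 1.10 to 2.27), and PXRKO vehicle had a median fold of 0.756 over WT vehicle in the 5 genes. Genotype and experiment are confounded, so a need for PXR and a difference between experiments in dosing or fasting cannot be told apart here.

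Nr1i2 kept reads in every PXRKO library. A WT library labelled PXRKO is argued against, since the highest PXRKO library (659) lay below the lowest WT library (1068). Reads from the part of the gene that the deletion leaves are a candidate explanation for the remaining 0.482 of the WT vehicle level. Counts per gene do not show which exons the reads come from, so this stays open.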

How the results depend on the processing

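No named gene that was called reversed its direction under the alternatives run. With PCN the 459 genes became 761 with DESeq2, 822 at an adjusted p of 0.1 and 110 with an absolute log2 fold change of at least 1, while DESeq2 size factors (456), no filter (498), a mean of at least 50 (477) and, chosen after seeing the data, unlisted genes counted as tested (418) moved it less. For the authors' calls, edgeR on the listed genes gave 792 against 1333 for atorvastatin, 2 against 28 for pravastatin (717 at an unadjusted p under 0.05), 0 against 12 for atorvastatin in PXRKO mice (537 at an unadjusted p under 0.05), 105 against 307 between vehicle groups and 951 against 1374 between atorvastatin groups. The cause was not tested. With an absolute log2 fold change of at least 1, on the authors' moderated values, these became 81, 0, 0, 19 and 127. At an adjusted p of 0.1 PXRKO atorvastatin had 19. Animal-number range as a covariate left 0 pravastatin genes in edgeR. The correlation of atorvastatin and PCN ratios was 0.862 with controls split, against 0.915. With an estimated correlation, adjusted p for PCN rose to 0.739 for the PXR/CAR, oxidation, heat shock and Kupffer lists and 0.517 for the clock, unfolded protein and mitochondrial lists. At a mean of at least 50 the male-biased list between vehicle groups had adjusted p = 0.0725 and the adipose list 0.227, with fewer genes counted. Leaving out 1 library gave 223 to 480 genes for PCN (266, 291 and 285 without vehicle libraries 1, 2 and 3, and 223 and 262 without PCN libraries 2 and 4). By edgeR on the listed genes it gave 458 to 658 for atorvastatin (458 and 524 without vehicle libraries 1 and 3, and 466 and 490 without atorvastatin libraries 1 and 3), 0 to 2 for pravastatin (2 only without pravastatin library 3, otherwise 0) and 0 to 0 in PXRKO mice. Between vehicle groups it gave 38 to 146 (47, 42, 57 and 68 without WT libraries 1 to 4). Counts of 146, 38, 56 and 58 came without PXRKO libraries 1 to 4, only the first above the 105 of all libraries. Between atorvastatin groups leaving out 1 library gave 585 to 864 (603 and 585 without WT libraries 1 and 3, and 633, 628 and 623 without PXRKO libraries 1, 3 and 4). For tests of a difference it gave 30 to 45 for the interaction, 50 to 70 for atorvastatin against pravastatin and 25 to 89 for atorvastatin against PCN (34 and 25 without PCN libraries 1 and 2, and 41 and 29 without atorvastatin libraries 1 and 3). For these DESeq2 gave 44, 71 and 96 and TMM on the shared genes 45, 72 and 69. The direct test of atorvastatin against PCN, and TMM for the statins, were chosen after seeing the data. Of named genes 32 of 46 kept their call for PCN whichever library was left out, 38 of 61 for atorvastatin, 0 of 16 for pravastatin, 0 of 9 in PXRKO mice, 17 of 50 between vehicle groups and 47 of 66 between atorvastatin groups, and 0 reversed. Not run were TMM, DESeq2 size factors and no filter for tables of selected genes, the animal-number covariate where columns are not tied to animals, and an adjusted p of 0.1 between atorvastatin groups. Depth of 6.64 M counts in vehicle library 3 and of 8.75 and 8.16 M in PCN libraries 2 and 3 limits genes of low level.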

Other observations

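The tests in this part were chosen only after the results were seen. Some genes of the unfolded protein and stress response list were called lower with atorvastatin in WT mice (9 of 27), with atorvastatin in PXRKO mice (2 of 26) and with PCN (4 of 27, with adjusted p = 0.517 for the list at an estimated correlation). In PXRKO mice 12 genes of the list were lower and 1 higher (Asns) among the genes of the least filtered table, with a median fold of 0.736 over all 13, and 8 of the 12 were also called lower in WT mice with atorvastatin and 5 with PCN in the authors' deposited table (2 with PCN by edgeR). Hspa5 stood at 8929.7 ± 1764 in WT vehicle, 6186 ± 1003 with atorvastatin and 6643 ± 529.8 with PCN, and Manf at 771 ± 150.0, 451 ± 99.4 and 483 ± 57.6 (SD, n = 4). In PXRKO mice the means of both genes were lower with atorvastatin as well, at 7251 ± 1019 and 522 ± 102 against 9619 ± 1702 and 821 ± 183 (SD, n = 4). In the interaction test (edgeR) 0 of 11 of these genes differed, which does not show that the genotypes respond alike. Vehicle library 3 was the highest WT vehicle library in 20 of 29 genes, and PXRKO vehicle library 4 the highest of its group in 10 of 13. Without them the median folds were 0.825 for PCN, 0.768 for atorvastatin and 0.769 in PXRKO mice, against 0.740, 0.714 and 0.736. These libraries were picked for being highest, so a move toward 1 was set in advance and does not measure their share. Without them the treated mean was lower in 26 of 29, 14 of 15 and 12 of 13 genes, the last 2 sets being listed genes only. Only 2 of these genes passed the authors' threshold in PXRKO mice, and 0 passed by edgeR on the listed genes.

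Of 28 pravastatin genes 23 were called in the same direction with atorvastatin, where independent lists would share 2.68, and 18 with PCN, where they would share 1.56. The vehicle libraries are shared by these comparisons, which raises such overlaps without any common effect: in 20 simulated data sets without effects, as many genes of the lowest p shared 12 to 19 (mean 15.7) and 10 to 18 (mean 12.7). The overlap with PCN lies within the simulated range and that with atorvastatin above it. The observed overlaps are of the authors' DESeq2 calls, while the simulated ones rank genes by edgeR in only 20 data sets. A common effect of pravastatin and atorvastatin therefore cannot be read from this gap.

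For whole comparisons, other splits of the same libraries were counted. With PCN 1 of 35 splits, the real one, gave as many as 459 genes, and the highest other gave 1. This argues against chance but does not exclude it, since 1 of 35 is the smallest share these splits can give. They also cannot part the compound from anything else that differed between the groups. For atorvastatin against pravastatin the real split of the 8 libraries fitted alone gave 62 genes and the highest other 4 (1 of 35 as large), and for atorvastatin against PCN 55 and 8 (1 of 35 as large). These genes were selected on calls that separate the same libraries, so chance cannot be excluded from these splits. For the authors' call counts no splits were run, since the genes were selected on the real split.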
